A study of Mus musculus with 4 samples.

How the data were processed

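Liver RNA of Med1 floxed C57BL6/J mice, 5.5 weeks old, was measured 3 or 5 days after tail vein injection of an adenovirus. The virus carried either Med1, a subunit of the Mediator complex, or LacZ, the bacterial beta-galactosidase gene that served as the control. Each of the 4 combinations of virus and day is a group with 1 array, so that 4 arrays were analysed. The groups come from the submitters' titles. Per the labels' protocols, RNA was extracted with Trizol, cleaned on columns with a DNase step, checked on a Bioanalyzer, and labelled with biotin by the MessageAmp kit for Illumina arrays. The scanner software and any summary over beads are not given in the sources used here.

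Per the file headers, the deposited table was not normalized and held a probe intensity on a linear scale for each of 45281 probes. Beside each intensity, per the file headers, stood a detection p-value, which moves in steps of 1 over 936 and falls as the signal rises. The authors' series values were identical to these intensities, with a largest difference of 0 on every array, so they carry no normalization either, and their direction and linear scale are known from this match. Their medians were 153 for Ad-Med1 at day 3, 94.1 for Ad-LacZ at day 3, 164 for Ad-Med1 at day 5 and 100.4 for Ad-LacZ at day 5. Bead numbers and bead standard errors were not analysed here.

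Background correction and normalization used neqc of limma 3.58.1 in R 4.3.3. It infers the background from the detection p-values, applies normexp with an offset of 16, normalizes quantiles between arrays and takes log2. All differences are log2 values of Ad-Med1 minus Ad-LacZ. A probe counted as detected at a detection p under 0.01. Probes were named from the platform annotation, with symbols updated through the gene identifier in a table of the GRCm38.p6 assembly, which held 34807 of the identifiers (99.8%). In all, 34885 probes had 1 gene symbol, 18 had several and 10378 had none, and only the first kind was named. Of 19057 genes with a probe, 9566 were detected on at least 1 array. A gene with several probes was represented by the probe with the highest mean signal over the 4 arrays, and the text gives the opposite direction of a further detected probe at a day whose value is named, and some of the smaller sizes. Further computing used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

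With 1 array per group, differences at each day have no replicate check and no p-value per day is given; the number of arrays limits the precision. A gene counted as different at a day when the viruses differed at least 2-fold and its probe was detected on at least 1 of that day's arrays. The count of genes different in the same direction on both days was set beside the overlap that independent lists would give; the days share no array. The same 2-fold count was made for all 6 pairs of arrays. Where the dimmer probe was not detected, the fold is a lower bound and written as at least that size; its dim side is the higher of the probe's own value and the lowest detected signal of that array. No fold is given where that bound lies under 1.

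Both days together were tested with limma, as lmFit and eBayes on all 4 arrays with virus and day as terms, which leaves 1 residual degree of freedom, with a prior of 2.69. Adjusted p-values are Benjamini-Hochberg values. Nothing in the labels says whether the arrays came from separate animals or pools. The residual degree of freedom is the difference between the virus effects of day 3 and day 5, with no spread within a group. These p-values therefore set the virus effect against that difference, in these samples only. Each SE given beside an effect comes from the same eBayes fit, which shares the spread over genes, and is not a spread between replicates. A change of the effect with time counts as noise, and genes with like differences on both days pass more easily. Genes were also adjusted over each of 39 fixed gene lists alone, with no adjustment across lists. The verbs rose and fell are used only for a gene that passed this last test at an adjusted p under 0.05.

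The 29 pathway lists and 10 lists of cell type markers covered the cell cycle (S phase, G2 and mitosis, G1 cyclins, cell cycle inhibitors with p53 targets), regeneration factors, Mediator subunits, nuclear receptors with coactivators, fat metabolism (PPARalpha targets, PPARgamma targets, lipogenesis), cholesterol, bile acids, xenobiotics, glucose, amino acids, plasma proteins, the acute phase, interferon, antigen presentation, chemokines, ER stress, Nrf2 targets, ribosome biogenesis, oxidative phosphorylation, fetal and tumour markers, the circadian clock, sex-biased genes, both zonation patterns, and T, B, macrophage, neutrophil, stellate, endothelial, cholangiocyte, erythroid, platelet and other abdominal markers. A list is described by the median difference of its detected genes and by the percentile of that median among 10000 random lists of equal size, drawn within 20 bins of mean expression (random seed 20). Percentiles above 97.5 or under 2.5 are called outside the central 95%. Of the 78 percentiles, 43 lay outside it. Members at least 1.5-fold different in the same direction on both days were counted.

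Genes were named by a rule: every Med1 probe, the 10 highest and 10 lowest genes at each day, the 10 higher and 10 lower genes with the largest smaller change over both days, and up to 4 members of each list that changed by 1.5-fold or more on both days (otherwise its 2 brightest). Genes past the limma threshold over all genes would have been added, and there were none. The text leaves out genes of smaller change. Symbols of unnamed gene models were left out. The rule held 157 genes; genes outside it are said to have been chosen after their values were seen. The groups, lists, designs, naming rule and most alternatives were fixed before the data were examined.

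The procedure was tested on simulated data made from the 9566 detected genes, with 200 genes changed and a spread between arrays of 0.401. That spread was the same for every gene and independent between genes, and every probe counted as detected. Measured genes differ in spread and vary together within lists, so the shares below do not give the power or false rate in the measured data. The 2-fold rule on both days recovered 20% of genes changed by 1 on the log2 scale, 94% of those changed by 2 and 100% of those changed by 3. For the limma test of the virus over both days, the shares were 16%, 90% and 100%. Of 9366 unchanged genes, 0.235% and 0.032% were called. Of 100 lists of 30 genes shifted by 0.5, 99% lay outside the central range, against 2% of unshifted lists.

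Alternatives tried were a normexp offset of 50, no background correction, scaling to a common median of detected probes, the series values, other detection filters, the mean of a gene's probes, a 1.5-fold threshold, the fit without the day term, an intensity trend in eBayes, and leaving out each array (in the fit without the day term, since with it no residual degree of freedom is left). Chosen after seeing the data were undetected signals set to the lowest detected one, each Ad-LacZ array as the control of the other day, genes with several probes, and the series values less their median difference. Scaling to a common median moved the median difference of all genes to -0.24 at day 3 and -0.13 at day 5, from -0.03 and 0.07. Changes are therefore read relative to all genes.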

Results

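The data describe the livers of Med1 floxed mice 3 and 5 days after an intravenous adenovirus that carried Med1 (Ad-Med1) or LacZ (Ad-LacZ). Med1 encodes a subunit of Mediator, the complex that joins transcription factors, nuclear receptors among them, to RNA polymerase II. The series title names the induction of cell proliferation as its subject. Each group held 1 array. Ad-Med1 arrays were brighter, with mean signals of 925 at day 3 and 968 at day 5 against 350.2 and 475 on the Ad-LacZ arrays. Detected probes numbered 14752 and 15294 on the Ad-Med1 arrays of day 3 and day 5, and 12899 and 14062 on the Ad-LacZ arrays.

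The first comparison asks whether Med1 RNA was higher after Ad-Med1. Med1 probe ILMN_2658227 had a log2 signal of 11.16 at day 3 and 12.22 at day 5 in Ad-Med1, and was not detected on either Ad-LacZ array, so that Ad-Med1 was at least 20.9-fold and at least 56.2-fold higher. Probe ILMN_3106388 was 4.23-fold and 4.56-fold higher. ILMN_1220563, the probe with the highest mean signal over the 4 arrays, was higher by 1.99 on the log2 scale at day 3 and by 0.20 at day 5. On no array were 2 further probes detected. Which Med1 probes lie within the part carried by the virus is not given in the sources used here. Among Mediator subunits as a group, the median difference was -0.17 at day 3 (percentile 28.3) and -0.08 at day 5 (percentile 22.9), and turned above 0 in the series values less their median difference (0.14 on each day). Med10 and Med25 were the only 2 of 28 measured subunits at least 1.5-fold lower on both days, with Med10 at -1.24 and -0.75. A second probe of Med25 was higher by 0.40 at day 5. None was higher on both days with Med1 counted by ILMN_1220563, while its probes ILMN_2658227 and ILMN_3106388 were higher on both.

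**Figure D1:**
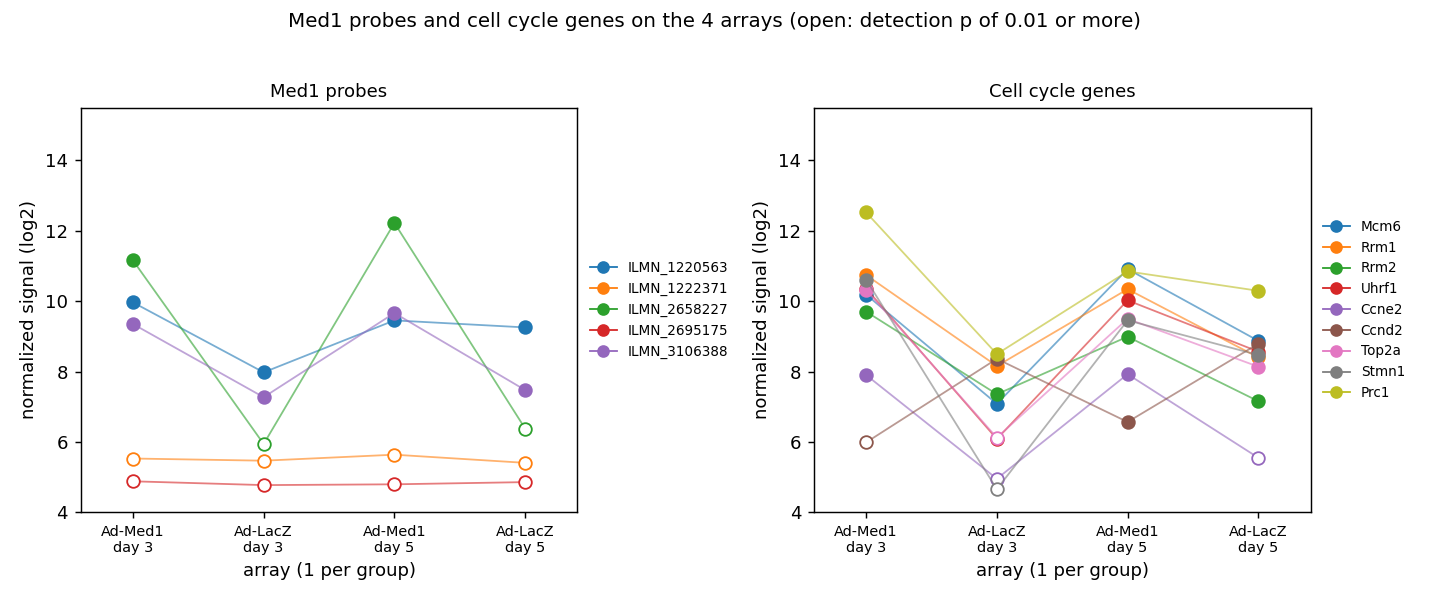
Normalized signal (log2) of each Med1 probe (left) and of 9 cell cycle genes (right) on the 4 arrays, with open points where the probe was not detected and lines joining the values of a probe. Probe ILMN_2658227 of Med1 stands at 11.16 and 12.22 on the Ad-Med1 arrays, and Prc1 at 12.52 on Ad-Med1 day 3 against 8.50 on Ad-LacZ day 3.

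At day 3, genes of cell division were higher in Ad-Med1 than in Ad-LacZ. The G2 and mitosis list had a median 9.43-fold higher (3.24 on the log2 scale, percentile 100), and 29 of its 30 measured genes were at least 1.5-fold higher. Ad-LacZ day 3 detected 14 of the 30, so this size rests in part on background. With undetected signals at the lowest detected one the median was 2.79 (percentile 100). Stmn1, which destabilises microtubules, was at least 14.2-fold higher and Top2a, the topoisomerase that untangles replicated DNA, at least 11.6-fold. Nusap1 and Prc1, which bundle spindle microtubules, were 17.3-fold and 16.3-fold higher. The S phase list had a median 3.97-fold higher (1.99, percentile 100), with 27 of 32 genes at least 1.5-fold higher. Ad-LacZ day 3 detected 22 of the 32, and with undetected signals at the lowest detected one the median was 1.56 (percentile 100). In the S phase list, Uhrf1, which keeps DNA methylation through replication, was higher by at least 3.58 on the log2 scale, and Lig1, the ligase that joins Okazaki fragments, was 10.6-fold higher.

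Cell cycle inhibitors and p53 targets were higher at day 3 too, with a median of 0.88 (percentile 99.9) and 10 of 16 genes at least 1.5-fold higher, among them Gadd45a at least 9.73-fold and Phlda3 at least 4.49-fold; Tnfrsf10b, a death receptor, was 1.80-fold lower. Their day 5 median was 0.22 (percentile 81.2). Beside these groups, the Ad-LacZ day 3 array stood apart from the others in Atp5a1 and Ndufb9, 2 parts of the respiratory chain chosen after their values were seen, which read 10.04 and 9.30 there against 12.89 to 13.33 and 11.98 to 12.52 on the other arrays. Brighter ones, Atp5b at 15.07 against 14.72 to 14.96 and Ndufa4 at 14.36 against 14.16 to 14.21, did not read low, and 9 of 37 oxidative phosphorylation genes were at least 1.5-fold higher at day 3. A second probe of Atp5a1 differed by -0.41 at day 3. With the Ad-LacZ day 5 array as the control of Ad-Med1 day 3, the S phase and mitosis medians were 1.12 and 1.90 (percentile 100 for each), and that of the p53 targets 0.36 (percentile 94.6). Stmn1, Top2a, Nusap1, Prc1, Uhrf1 and Lig1 then stood at 2.14, 2.18, 2.24, 2.23, 1.79 and 1.54, and Gadd45a and Phlda3 at 1.99 and 1.11.

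Markers of resident macrophages and red cells were lower in Ad-Med1 at day 3. Vsig4 and Clec4f, receptors of Kupffer cells, were not detected and at least 62.8-fold and 39.2-fold lower than in Ad-LacZ. Of 22 macrophage markers measured, 15 were at least 1.5-fold lower, and the list median was -1.52 (percentile 0). Haemoglobin transcripts were low on this array alone, with Hba-a1 at 9.10 against 14.06 to 14.63 elsewhere and Hbb-bt at 9.67 against 14.00 to 14.58; Hbb-bs differed by -4.46 at day 3. The erythroid list had a median of -0.90 (percentile 0.27). The Ad-LacZ day 3 array was the high one for both Kupffer cell receptors, with Clec4f at 11.51 against 8.61 and 8.68 at day 5 and Vsig4 at 12.19 against 7.77 and 6.97. With Ad-LacZ day 5 as the control they differed by -3.09 and -1.19, and the macrophage list by -1.13 (percentile 0). Platelet markers went the other way, with Pf4 at least 5.18-fold and Ppbp at least 2.93-fold higher; Ad-LacZ day 3 detected none of the 3 genes, so their median of 3.23 (percentile 99.8) rests on background and was at least 1.55 (percentile 99.7). Against Ad-LacZ day 5 it was 0.45 (percentile 71.5).

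Genes of xenobiotic metabolism were higher at day 3, with a median of 0.63 (percentile 100) and 19 of 36 genes at least 1.5-fold higher. The largest differences lay in enzymes that livers of female mice express above those of males: Sult2a2 was at least 58.9-fold, Cyp2a4 at least 57.2-fold and Cyp2b13 at least 26.9-fold higher. Cyp2c29, another cytochrome of this list, was 19.5-fold higher, and D17H6S56E-5, a transcript outside it, at least 28.7-fold. Hsd3b5, a male-biased steroid dehydrogenase, was 121-fold lower, and Cyp4a12b, a male-biased fatty acid hydroxylase, 35.7-fold lower. With Ad-LacZ day 5 as the control, Sult2a2, Cyp2a4, Cyp2b13 and Cyp2c29 stood at 0.53, 0.36, -0.52 and -0.08, D17H6S56E-5 at 2.45, and Hsd3b5 and Cyp4a12b at -4.68 and -1.90. Sex-linked transcripts moved with these genes. Xist, transcribed from the inactive X chromosome, was detected on Ad-Med1 day 3 and not on Ad-LacZ day 3, while Y-linked Eif2s3y was detected on Ad-LacZ day 3 (9.52) and not on Ad-Med1 day 3. At day 5 Ad-Med1 carried both and Ad-LacZ only Xist; Xist probes disagreed there, with virus differences from -4.67 to 1.36. A probe of Y-linked Uty, chosen after its value was seen, was detected on Ad-LacZ day 3 (7.39), Ad-Med1 day 5 (6.93) and, near background, Ad-Med1 day 3 (6.32). The day 3 arrays thus differed in Xist and Eif2s3y as well as in virus, and sex cannot be told apart from virus in the differences between them. The xenobiotic list had a median of -0.14 at day 5 (percentile 12.3), and one of -0.07 at day 3 when Ad-LacZ day 5 was the control. The sex-biased list, which holds genes of both sexes, had medians of -0.21 (percentile 11.6) and -0.28 (percentile 1.54), and 4 of its genes stand on the xenobiotic list; with Ad-LacZ day 3 as the control of Ad-Med1 day 5 it turned to 0.83.

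In all, 1576 genes were at least 2-fold higher and 1085 at least 2-fold lower at day 3, of 9052 tested (29.4%). Of these, 859 were not detected in Ad-LacZ and 272 not in Ad-Med1. Higher genes made up 59.2% of those counted, and 38.6% after scaling to a common median. With Ad-LacZ day 5 as the control, the counts were 841 and 603.

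**Figure D2:**
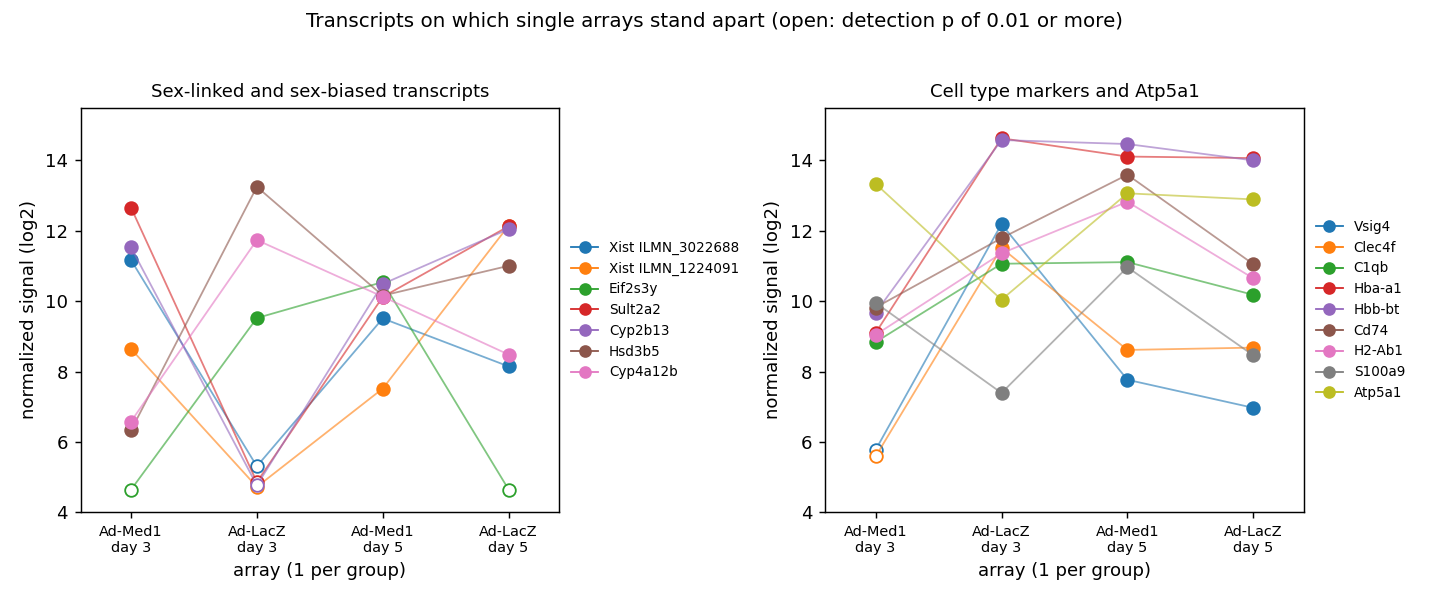
Normalized signal (log2) of sex-linked and sex-biased transcripts (left) and of cell type markers with Atp5a1 (right) on the 4 arrays; open points were not detected. Hba-a1 reads 9.10 on Ad-Med1 day 3, and Atp5a1 10.04 on Ad-LacZ day 3.

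At day 5, genes of antigen presentation and of T cells were higher in Ad-Med1. Ubd, a ubiquitin-like protein induced by interferon gamma, was 64.7-fold higher and Cxcl9, a chemokine that draws T cells, 10.3-fold. All 15 measured T and NK cell markers were detected in Ad-Med1 and 7 in Ad-LacZ, 14 of them were at least 1.5-fold higher, and the median was 1.49 (percentile 100; 0.96 with undetected signals at the lowest detected one, and 0.31 with the series values less their median difference). Cd8b1, a chain of the CD8 receptor, was 2.67-fold higher, and Prf1, the perforin of killer cells, 2.40-fold lower (0.50 and -0.44 with Ad-LacZ day 3 as the control). The antigen presentation list had a median of 1.45 (percentile 100) with 10 of 15 genes at least 1.5-fold higher. Chosen after their values were seen, Cd74 and H2-Ab1, the invariant chain and a beta chain of MHC class II, were 5.81-fold and 4.52-fold higher. At day 3 the medians of these lists were -0.15 (percentile 21.2; 0.08 when every array had to detect the gene) and -0.27 (percentile 12.1; -0.56, percentile 0.81, with undetected signals at the lowest detected one). Against Ad-LacZ day 5 they were -0.31 (percentile 3.09) and -1.05 (percentile 0).

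Interferon response genes had a median of 0.72 at day 5 (percentile 100), with 25 of 44 at least 1.5-fold higher, against 0.11 at day 3 (percentile 82.3), which was below 0 after median scaling (-0.16). Irf8 and Trim30a were higher by 1.44 and 1.19 at day 5; at day 3 they were higher too, but stood at -0.07 and -0.39 with Ad-LacZ day 5 as the control, as the interferon list did at -0.49 (percentile 0). Chemokines and adhesion molecules had medians of 1.30 (percentile 100; 0.71 and 0.23 under the same 2 processings) at day 5 and 0.18 (percentile 70.3) at day 3, the latter below 0 after median scaling (-0.73) and against Ad-LacZ day 5 (-0.42, percentile 0.61). In that list Cxcl1, which draws neutrophils, was 12.3-fold higher at day 5. Outside the immune lists, Cbr3, a carbonyl reductase, was 32.0-fold higher at day 5, Asns, which makes asparagine, 11.6-fold, and Plin4, which coats lipid droplets, at least 11.5-fold (0.68 on the log2 scale with Ad-LacZ day 3 as the control). Of the macrophage markers, 12 of 22 were at least 1.5-fold higher at day 5, with a median of 0.61 (percentile 99.9; 0.42, percentile 96.9, against Ad-LacZ day 3), and Ly6c1 was 3.80-fold higher. The list shares 1 gene with antigen presentation.

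Cell division genes were higher at day 5 as well, by less against that day's control. The S phase median was 0.53 (percentile 99.9), with 15 of 32 genes at least 1.5-fold higher, and the mitosis median 0.46 (percentile 98.7), with 9 of 30. The mitosis list left the outer range under 6 other processings, in which its percentile lay between 75.8 and 97.4. With Ad-LacZ day 3 as the control of Ad-Med1 day 5, the S phase and mitosis medians were 1.51 and 1.53 (percentile 100 for each), so the smaller size depends on the control array. The replication-dependent histones H2ac22, H2ac15 and H2ac12 were 11.7-fold, 7.80-fold and 7.65-fold lower, and stood at -0.60, -1.06 and -0.87 with Ad-LacZ day 3 as the control. Dnaic1, a dynein chain of cilia, was 19.3-fold lower and Dct, an enzyme of pigment synthesis, 9.69-fold; Loxl4, which crosslinks collagen, was 7.77-fold lower (-1.02 with the other control). In all, 943 genes were at least 2-fold higher and 711 at least 2-fold lower at day 5, of 9261 tested (17.9%); 404 and 171 of them were not detected in the lower group. The higher share was 57.0%, and 30.2% after scaling to a common median. With Ad-LacZ day 3 as the control the counts were 1668 and 1082.

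Over both days, 34 genes passed the limma test within 14 of the lists. DNA synthesis genes rose: Mcm6, a part of the replicative helicase, rose 5.94-fold (2.57 ± 0.41 SE on the log2 scale, adjusted p = 0.0444 over the list alone), and the ribonucleotide reductase subunits Rrm1 and Rrm2, the latter chosen after its value was seen, rose 4.80-fold and 4.26-fold (adjusted p = 0.0444 for each). The other 29 measured S phase genes did not pass. Among G1 genes, cyclin Ccne2, named after its value was seen, rose 6.33-fold (at least 2.18-fold and 2.86-fold at day 3 and day 5, since Ad-LacZ did not detect it) and Ccnd2 fell 4.92-fold (adjusted p = 0.0194 for each). The G1 list had medians of 0.53 (percentile 97.7) and 0.58 (percentile 99.7), with 6 of 18 genes higher and 1 lower on both days, Ccne1, Id1 and E2f1 among the higher ones (1.25, 0.75 and 0.89 at day 5). Over other processings its day 3 median fell as far as 0.06 and the percentile as far as 84.7, inside the central range. No mitosis gene passed (smallest adjusted p = 0.145). Mcm6 was higher by 3.10, at least 2.52 and at least 1.92 at day 3 on its 3 probes detected there. Its call was lost when the day term was dropped. In fits without that term, Rrm1, Rrm2, Ccne2 and Ccnd2 lost theirs without Ad-Med1 day 3.

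**Figure D3:**
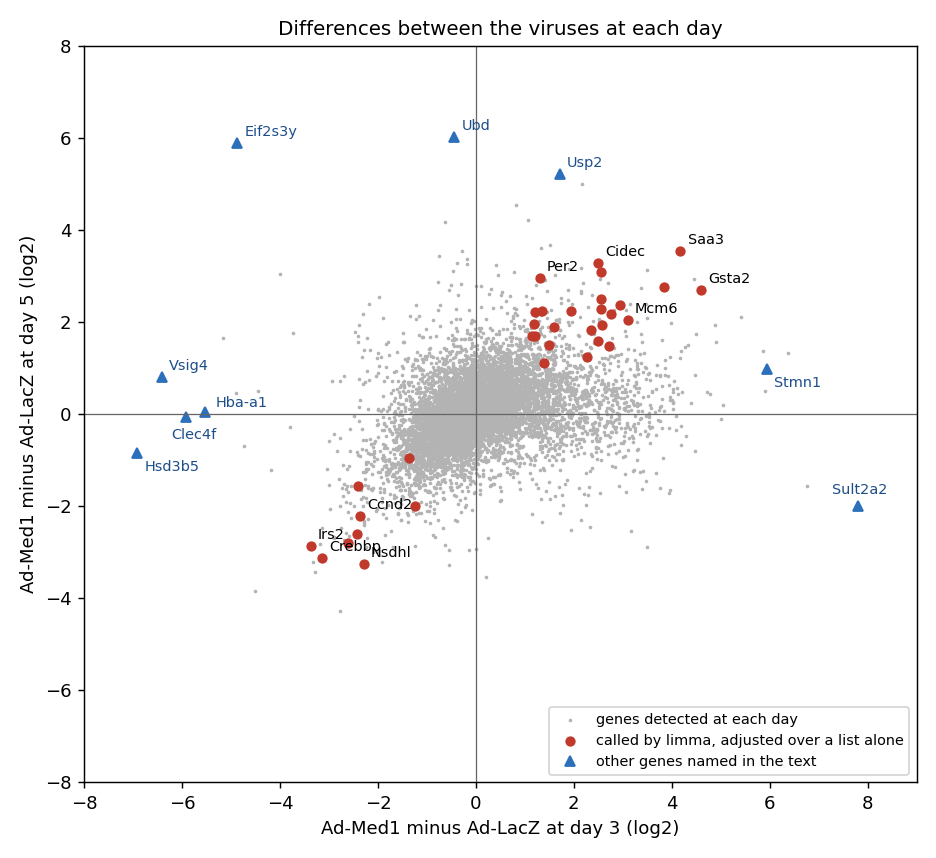
Differences between Ad-Med1 and Ad-LacZ (log2) at day 3 (horizontal) and day 5 (vertical), a point per gene detected on at least 1 array at each day. Red points, the genes called by limma when adjusted over a list alone, lie in the same direction on both days, as Saa3 does at 4.18 and 3.55. The test favours such genes, since its residual is the difference between the days. Blue triangles are other named genes.

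Some acute phase genes and most neutrophil genes rose over both days. Saa3, a serum amyloid made in inflammation, rose 14.5-fold (3.86 ± 0.34 SE, adjusted p = 0.0149 over the list alone), and the calprotectin subunits S100a9 and S100a8 rose 5.79-fold and 4.28-fold. Ly6d rose 7.08-fold (at least 3.91-fold at day 3) and Steap4, a metalloreductase named after its value was seen, 5.52-fold (at least 1.52-fold and 2.43-fold by day). These were 5 of 30 acute phase genes; 11 were at least 1.5-fold higher on both days and none lower. The list medians were 0.32 (percentile 99.4) and 0.72 (percentile 100), the first turning to -0.43 after median scaling. Of 13 neutrophil markers, 8 rose, 3 of which also stand on the acute phase list (S100a8, S100a9, Lcn2), and the medians were 2.82-fold higher on both days (percentiles 99.9 and 100). Ad-LacZ detected 4 of the 13 at day 3, where the median, 1.49 on the log2 scale, was 0.73 with undetected signals at the lowest detected one; with the series values less their median difference the medians were 0.37 and 0.62 (percentiles 99.9 and 100). Chil3, a chitinase-like protein, rose 4.27-fold (at least 1.66-fold at day 3, where Ad-LacZ did not detect it) and Lcn2, an iron carrier of granules, 2.75-fold. The granule genes Camp, Ltf and Ngp and the resistin-like Retnlg, chosen after their values were seen, rose by 1.79, 1.74, 1.43 and 1.49 on the log2 scale. All 4 of them were undetected in Ad-LacZ at day 3, so that these values rest in part on background: the day 3 bounds were 0.24 for Camp and 0.19 for Retnlg, and below 0 for Ltf and Ngp. With the series values less their median difference their day 3 values were -0.07, -0.20, -0.43 and -0.07. Dropping the day term ended the neutrophil calls of Chil3, Ltf, Ngp and Retnlg and the acute phase call of S100a8. In fits without that term, the other 4 neutrophil calls were lost without Ad-LacZ day 3 and without Ad-Med1 day 5. Over the acute phase list, Saa3 and Ly6d lost theirs without Ad-Med1 day 5, Steap4 without either Ad-Med1 array, and S100a9 without each array but Ad-LacZ day 5.

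Of 16 clock genes, 6 rose as well. Nr1d2, the receptor REV-ERB beta that represses Arntl, rose 5.33-fold (2.41 ± 0.31 SE, adjusted p = 0.031 over the clock list alone) and Per2, a repressor of the clock, 4.38-fold (adjusted p = 0.0473). Per3, Tef, Bhlhe40 and Wee1, chosen after their values were seen, rose by 1.72, 1.57, 1.25 and 1.75, but Ad-LacZ detected Per3 and Wee1 on neither day. Their bounds were 0.35 and 0.75 for Per3 and 0.32 and -0.18 for Wee1, and Per3 at day 3 and Wee1 at day 5 turned to -0.04 and -0.19 with the series values less their median difference. The clock list had medians of 0.92 (percentile 99.9) and 1.64 (percentile 100), which exchanged controls turned to 2.15 and 0.87, and 9 of 16 genes were higher and 2 lower on both days. Over other processings the day 3 median fell as far as 0.35 and its percentile as far as 90.9, inside the central range. Usp2, a deubiquitinase driven by the clock, was 3.29-fold higher at day 3 and at least 31.1-fold at day 5, and Per1 2.09-fold and 18.7-fold; with exchanged controls they stood at 4.98 and 3.81 at day 3 and at 1.96 and 1.481 at day 5. Arntl, which activates the Per genes and was chosen after its value was seen, differed by -0.64 and -2.85 (-3.30 and -0.19 with exchanged controls). Nr1d1, REV-ERB alpha, was 2.33-fold and 2.08-fold lower. With exchanged controls it stood at 0.14 and -2.41. In fits without the day term, the 6 calls were lost without either Ad-Med1 array.

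Nuclear receptors and coactivators had medians near 0 (-0.22, percentile 16.5, and -0.17, percentile 7.45), with 7 of 27 genes lower and 1 higher on both days. Crebbp, the acetyltransferase CBP, fell 8.77-fold (-3.13 ± 0.30 SE, adjusted p = 0.0187 over the list alone) and was not detected in Ad-Med1, at least 3.95-fold and 4.34-fold lower at day 3 and day 5. Ppargc1a, a coactivator of fasting metabolism, was 6.54-fold and 2.16-fold lower. Nr1d2, on this list too, was the 1 higher gene (adjusted p = 0.0262). Irs2, which carries the insulin signal and stands on the glucose list, fell 8.71-fold (-3.12 ± 0.33 SE, adjusted p = 0.0201 over the glucose list alone, and at least 6.77-fold at day 5), a call lost when the day term was dropped. In fits without that term, Crebbp stayed called with any array left out, and Nr1d2 lost its call without Ad-Med1 day 3.

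Some glutathione transferases rose, and the median of the Nrf2 targets was higher on both days. Gsta2 rose 12.5-fold, Gsta1 9.90-fold and Gstm3, named after its value was seen, 4.13-fold (adjusted p = 0.0394, 0.0342 and 0.0462 over the Nrf2 list alone). They were 3 of 19 genes; the medians were 0.58 (percentile 99.9; 0.27, percentile 96.5, against Ad-LacZ day 5) and 0.63 (percentile 100), the latter -0.22 (percentile 93.2) after median scaling, and 6 of the genes, these 3 among them, also stand on the xenobiotic list. Ad-LacZ did not detect Gstm3 at day 3 (at least 0.58 on the log2 scale). The 3 calls were lost when the day term was dropped, and with Ad-LacZ day 5 as the control the day 3 values of Gsta2, Gsta1 and Gstm3 were 1.93, 1.79 and 0.64. Within the xenobiotic list none passed (smallest adjusted p = 0.0647). Cidec, which enlarges lipid droplets, rose 7.39-fold (adjusted p = 0.0223); Ad-LacZ did not detect it, and it was at least 2.17-fold and 5.13-fold higher by day and stayed called with any array left out in fits without the day term.

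Cholesterol and amino acid genes were lower. Nsdhl, an enzyme of sterol synthesis, fell 6.82-fold (-2.77 ± 0.39 SE, adjusted p = 0.0415 over the list alone), the only 1 of 15 cholesterol genes to pass, a call lost, in fits without the day term, without each array but Ad-Med1 day 3. Mvd, Pmvk and Lss of the same pathway were 2.36-fold, 2.41-fold and 1.91-fold lower at day 3 and 7.26-fold, 3.56-fold and 3.99-fold lower at day 5. The cholesterol medians were -0.68 (percentile 0.35) and -1.48 (percentile 0), with 8 genes lower and none higher on both days. For amino acid metabolism and the urea cycle they were -0.67 and -0.68 (percentile 0 on each day), with 10 of 24 genes lower; Hpd, of tyrosine breakdown, was 4.98-fold and 3.98-fold lower. Bile acid genes had medians of -0.28 (percentile 6.57) and -0.51 (percentile 0.05), or -0.41 (percentile 0.15) and -0.37 (percentile 3.58) with exchanged controls, and Cyp8b1, which makes cholic acid, was 2.88-fold and 4.91-fold lower. Pericentral genes had medians of -0.62 (percentile 0.5) and -0.99 (percentile 0), with 7 of 13 lower. Over other processings the day 3 median reached -0.15 and its percentile 22.4, inside the central range. Of the pericentral genes, 2 also stand on the amino acid list.

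Endothelial markers were lower, with medians of -0.84 (percentile 0.01) and -0.53 (percentile 0.21) and 7 of 18 lower on both days; Vwf, the clotting factor stored in endothelium, was 2.97-fold and 2.94-fold lower. Among stellate cell and matrix genes, Lrat, which stores retinol as esters, fell 6.54-fold (-2.71 ± 0.30 SE, adjusted p = 0.0219 over the list alone) and was not detected in Ad-Med1 (at least 5.34-fold and 5.15-fold lower by day), a call lost without Ad-Med1 day 5 and the day term; the list medians were -0.52 (percentile 1.49) and -0.25 (percentile 4.55). Rgs5, a regulator of G protein signalling found in pericytes, was at least 16.3-fold and 10.2-fold lower.

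**Figure D4:**
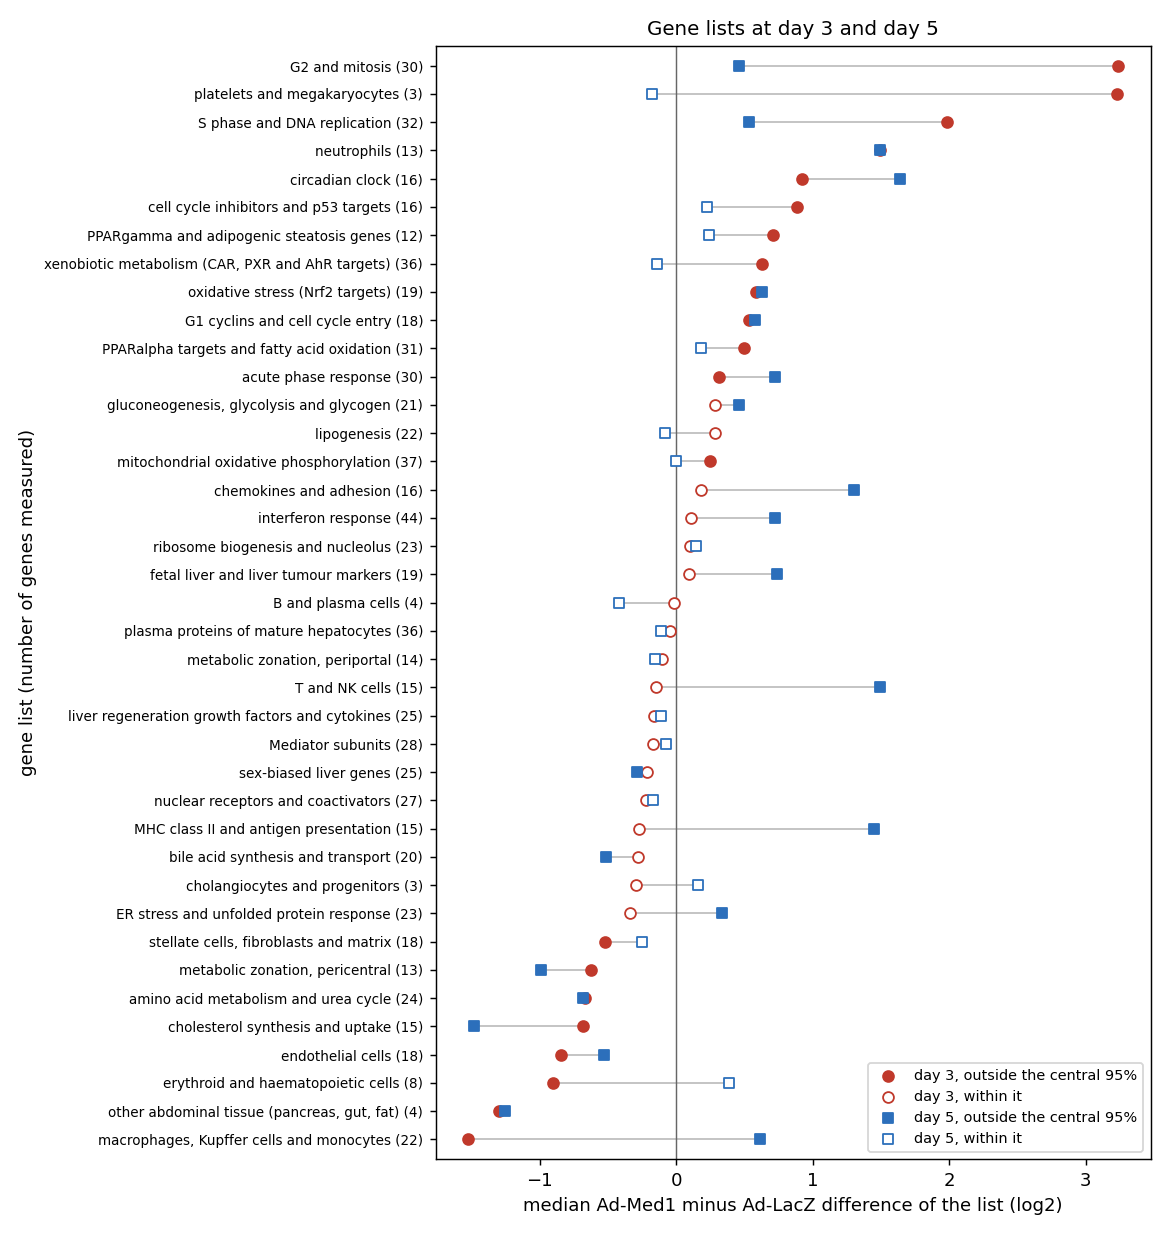
Median difference between Ad-Med1 and Ad-LacZ (log2) of each of 39 gene lists at day 3 (red circles) and day 5 (blue squares), filled where the median lies outside the central 95% of matched random lists. The mitosis list stands at 3.24 at day 3 and 0.46 at day 5, and the macrophage list stands at -1.52 and 0.61.

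On both days, 302 genes were at least 2-fold higher and 299 at least 2-fold lower, against 133 and 72.3 for independent lists, and 116 went in opposite directions. Across the 8747 genes tested on both days, which are not independent replicates, the differences correlated with Pearson's r of 0.35 and Spearman's rho of 0.41. In limma, 0 of 9566 genes passed an adjusted p under 0.05 for the virus (smallest 0.366); at an unadjusted p under 0.05, 646 were higher and 649 lower. For day 5 against day 3, 0 genes passed as well, with 141 higher and 53 lower at an unadjusted p under 0.05. The 38 calls over lists alone (34 genes) therefore pass in their lists and not over all genes tested. Fits that leave out an array have no day term, since with it no residual degree of freedom is left; dropping that term alone kept 28 of the 38. Of these 28, 12 remained without Ad-Med1 day 3, 21 without Ad-LacZ day 3, 7 without Ad-Med1 day 5 and 27 without Ad-LacZ day 5.

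Among the genes with the largest differences on both days outside these lists, Eif4ebp2, which represses translation, was 10.1-fold lower at day 3 and 9.28-fold at day 5. The noncoding Hectd2os was 9.72-fold and at least 7.47-fold lower, Bach1, a repressor of haem oxygenase, 8.90-fold and 5.52-fold lower, Agxt, which clears glyoxylate, 7.41-fold and 6.43-fold lower, and Acat3 6.73-fold and 5.57-fold lower. On the higher side, Psat1, of serine synthesis, was at least 5.47-fold and 8.74-fold higher, Amn, a partner of the cubilin receptor, at least 6.06-fold and 5.42-fold, and Mbd1, which binds methylated DNA, 4.87-fold and 5.04-fold.

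Pairs of arrays that do not differ in virus give a size for such counts. Both Ad-LacZ arrays differed at least 2-fold in 1599 genes (18.6%), 557 of them higher at day 3, and both Ad-Med1 arrays in 735 (7.93%). Beside the day, the arrays of each pair differed in sex-linked transcripts. Eif2s3y was detected on Ad-LacZ day 3 and Ad-Med1 day 5 only, and Xist on every array but Ad-LacZ day 3. The Ad-LacZ pair is close to the 1654 genes between the viruses at day 5, the Ad-Med1 pair is below it, and both are below the 2661 at day 3. Where a gene had at least 2 detected probes, 44.6% of the genes higher and 48.2% of those lower at day 3 were so on every detected probe, and 47.1% and 44.8% at day 5. Actb, an actin used as a reference gene and named after its values were seen, differed by -1.27 to -4.91 over its 5 probes at day 3. Other probes of named genes gave smaller sizes: at day 3 the second probes of Clec4f, Top2a, Lig1 and Gadd45a stood at -2.35, 1.74, 2.01 and 1.88, and at day 5 that of Loxl4 at -0.87 and the lowest ones of H2-Ab1, Usp2 and Mbd1 at 1.03, 1.66 and 0.16.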

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

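The tests of RNA or labelling (its comparison with the Ad-LacZ pair included), of the animals' sex, of the Ad-LacZ day 3 array, of noise in the S phase and mitosis lists, of T cells at each day and of the hour of death were chosen after the result was seen. The intervals that keep some tests open were added after the values were seen as well, and so were the minimum of 3 clock genes per arm and the rule that a list mostly undetected decides nothing. Values of some cell cycle genes and of some genes with several probes had been looked at before the other tests were written.

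Several results changed direction between day 3 and day 5, and with 1 array per group these differences were not tested with replicates. The limma split of virus by day, with day left in the residual, called 0 genes, with 149 higher and 277 lower at an unadjusted p under 0.05. The macrophage list moved by 2.13, from -1.52 at day 3 to 0.61 at day 5 (-1.13 and 0.42 with exchanged controls). Where a side was not detected, the measured difference rests on background and its bound is given. Sult2a2 went from at least 5.88 (measured 7.80) to -2.01, a measured change of -9.81, and Cyp2b13 from at least 4.75 (measured 6.76) to -1.56 (-8.32). Cyp4a12b went from -5.16 to 1.64 (6.80), and Eif2s3y, undetected on Ad-Med1 day 3 and Ad-LacZ day 5, from a bound of -3.30 (measured -4.88) to at least 4.13 (measured 5.89; 10.8). Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, went from -4.00 to at least 1.93 (measured 3.05; 7.05), and Pf4 from at least 2.37 (measured 3.23) to -1.20 (-4.43). Among probes without a gene name, which the comparisons leave out, 83 were at least 2-fold higher and 120 lower on both days of 2283 detected. The smaller of the 2 days' differences was 4.55 for ILMN_2906728 and 3.17 for ILMN_1256343.

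Many genes differed in the same direction on both days. Among the lower ones 266 of 299 (89.0%) kept their 2-fold difference with undetected signals set to the lowest detected one. That argues against undetected signals on the Ad-Med1 arrays as the source of the lower genes. It does not test weak but detected signals on the dimmer Ad-LacZ arrays. Among the higher genes 187 of 302 kept theirs (61.9%, 95% interval 56.3 to 67.2), which leaves background on the Ad-LacZ arrays open. Noise of single probes stays open: further probes were all at least 1.5-fold different the same way on both days for 40 of 81 higher genes (49.4%; interval 38.8 to 60.1) and 47 of 88 lower genes (53.4%), the first value just below the 50% set in advance as a sign of noise. Probes of a gene moved apart between the viruses 4.16 times as much at day 5, and 8.28 times at day 3, as between the Ad-Med1 arrays in variance. Between the Ad-LacZ arrays that variance was 0.286, above the 0.219 between the viruses at day 5 and below the 0.436 at day 3. The Ad-LacZ arrays share their virus, so a spread of the day 5 size arose without Med1. How much of the spread between the viruses comes from RNA or labelling, and how much from Med1, cannot be told apart. The sex of the animals cannot be told apart for the shared genes. Female-biased less male-biased genes stood at 5.07 at day 3 and -0.61 at day 5 (interval -2.53 to 0.69). Opposite signs would go against sex as the cause, but the day 5 interval spans both signs. Y-linked Eif2s3y reversed as well, with bounds of -3.30 at day 3 and 4.13 at day 5. Xist probes disagreed at day 5, from -4.67 to 1.36.

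The S phase and mitosis lists were higher on both days. With Ad-LacZ day 5 as the control their day 3 medians were 1.12 and 1.90 (percentile 100 for each), which argues against a deviating Ad-LacZ day 3 array as the only cause and, with percentile 100 in every setting, against noise of single probes at day 3, while the share of that array in the day 3 size cannot be told apart from Med1, since 1.12 lies close to the 0.99 set as the limit. Cycling immune cells stay open at day 3. The T and NK cell median was -0.15 there, with 4 of the 15 markers detected in Ad-Med1 and 6 in Ad-LacZ. These values show no gain of T and NK cells, but by the rule given above a list mostly undetected decides nothing. At day 5 the T and NK cell median was 1.49, above the 0.27 needed, so cycling immune cells may contribute there. Over both days, the ratio to the S phase median was -0.0733 at day 3 and 2.80 at day 5 and decides nothing, and noise of single probes stays open at day 5, where a percentile fell to 75.8, and for single genes, of which 7 of 8 (87.5%; interval 52.9 to 97.8) were higher on every further probe. The sex of the animals was not tested for these lists and stays open on both days. Eif2s3y differed between the viruses on each day, Xist differed at day 3, and its probes disagreed at day 5. Ad-LacZ day 5, the other control, carried Xist and not Eif2s3y, as Ad-Med1 day 3 did. The medians of 1.12 and 1.90 thus compare arrays alike in the detection of these transcripts. They rest on a single control array of another day. Proliferation of hepatocytes after Med1 stays open and was not tested apart from these explanations.

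The clock list was higher on both days. A different hour of death could give this: genes of the output arm stood above those of the positive arm by 1.58 at day 3 and 4.24 at day 5. With 2 positive-arm genes measured, fewer than the minimum, and no hour of death given in the sources used here, it cannot be told apart from an effect of Med1 on the clock. The cause was not tested further.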

How the results depend on the processing

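The series values less their median difference, undetected signals at the lowest detected one, and the exchanged Ad-LacZ controls were tests chosen after the data were seen. Of the list medians outside the central range, 339 of 386 values under the alternatives other than exchanged controls stayed outside in the same direction, 46 came inside and 1 reversed. With exchanged controls 35 of 43 stayed, 6 came inside and 2 reversed. Of the medians inside the range, 34 of 345 values moved outside it. Weighting by bead standard errors was not run, since the table read here has none. No paired analysis was possible because the labels carry no replicate numbers, beyond the day term of the limma fit, which sets the viruses side by side within each day. Where no construction is named below, the cause was not tested. Signal over background limits the low end, where 859 of the day 3 higher genes were not detected in Ad-LacZ.

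Genes at least 2-fold higher and lower were 976 and 580 at day 3, 386 and 364 at day 5, and 105 and 143 on both days without background correction. After median scaling, 1717 were lower at day 3, 601 higher and 1390 lower at day 5, and 173 higher and 731 lower on both days. The unnormalized series values, which keep the brighter Ad-Med1 arrays, gave 7838 and 10 at day 3, 7703 and 10 at day 5, 6797 and 0 on both days, a correlation of 0.46 and 8958 limma calls. Less their median difference they gave 1024 and 570 at day 3, 540 higher at day 5, 190 and 192 on both days, and again 0.46. Requiring detection on every array left fewer genes: 717 higher at day 3, 539 at day 5 and 116 on both days. The lower 1.5-fold threshold gave 2368 and 2220, 2078 and 1619, and 843 and 846. Higher on both days were 194 with an offset of 50 and 187 with undetected signals at the lowest detected one. With Ad-LacZ day 5 as the control at day 3 the counts were 841 and 603, and with Ad-LacZ day 3 at day 5, 1668 and 1082. Leaving out 1 array gave 0 to 413 limma calls, the most without Ad-LacZ day 5; these fits have no day term, and a lone array is assumed to vary like the others.

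Calls over a list alone, 38 in the report, numbered 69 with an offset of 50, 72 without background correction, 138 after median scaling, 609 with the unnormalized series values, 87 with an intensity trend, and 37 to 174 with 1 array left out (49 without Ad-Med1 day 3, 60 without Ad-LacZ day 3, 37 without Ad-Med1 day 5, 174 without Ad-LacZ day 5), the last fits without the day term, which by itself gave 52. The day 5 mitosis median was 0.34 with an offset of 50, 0.24 with the series values less their median difference, 0.17 with detection on every array, 0.11 with no filter, 0.37 with the mean of probes and 0.30 with undetected signals at the lowest detected one. The day 5 S phase median was 0.34 (percentile 97.3) with the series values less their median difference. Lists above the central range on both days numbered 4 after median scaling, 2 with the series values less their median difference and 4 with undetected signals at the lowest detected one, against 7. In the last setting the day 3 medians of the G1, acute phase, clock and PPARgamma lists were 0.19 (percentile 88.9), 0.18 (percentile 95.8), 0.44 (percentile 98.7) and 0.50 (percentile 98.6). Lists below it numbered 3 with no filter, against 5. The other abdominal list had a day 3 median of -0.0144 with no filter. With exchanged controls the xenobiotic list stood at -0.0669 at day 3 and the sex-biased list at 0.83 at day 5. Lists that exchanged controls moved outside the range were also lipogenesis at 0.54 (percentile 100) and the sex-biased list at -0.43 (percentile 0.05) at day 3, and at day 5 the p53 targets at 0.73 (percentile 99.6), PPARalpha at 0.44 (percentile 100), PPARgamma at 0.66 (percentile 98.8) and xenobiotics at 0.87 (percentile 100).

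Med1 at day 5, 0.20 in the report, was 4.74 without background correction and 4.40 with the series values less their median difference because ILMN_2658227 had the highest mean signal there; ILMN_1220563, the probe of the report, stood at 0.17 and 0.47. It was 2.74 with the mean of probes and 1.476 with Ad-LacZ day 3 as the control; at day 3 it was 0.71 with Ad-LacZ day 5. Day 3 values that turned below 0 were Ngp at -0.13 after median scaling, -0.43 with the series values less their median difference and -0.55 at the lowest detected signal, Ltf at -0.20 and -0.19 under the last 2, and Camp, Retnlg and Per3 at -0.0716, -0.072 and -0.0377 under the former of these. Wee1 at day 5 was -0.19 and -0.18 under the same 2, and Xist -2.02 with the mean of probes. With Ad-LacZ day 5 as the control, day 3 values were Cyp2b13 -0.52, Cyp2c29 -0.084, Irf8 -0.0724, Mpeg1 -0.75, Nr1d1 0.14, Oasl2 -0.58, Ppp1r3g 1.76, Trim30a -0.39 and Uty 1.07. With Ad-LacZ day 3 as the control, day 5 values were Cyp2b13 5.72, Cyp4a12b -1.61, Pf4 1.57, Ppp1r3g -2.72, Sult2a2 5.26 and Uty -0.47.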

Other observations

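The lists of this part were fixed in advance, and no test of an explanation is added here. Among lists of fat metabolism, those of PPARalpha and PPARgamma were higher at day 3. PPARalpha targets had medians of 0.50 (percentile 100) and 0.18 (percentile 97.2), which were -0.21 and -0.50 after median scaling, a step that lowers the median of all genes too: the day 3 percentile was 99.4 then and no lower under any alternative but exchanged controls; Acot3, a thioesterase of peroxisomes, was 14.6-fold higher at day 3. PPARgamma and steatosis genes had medians of 0.71 (percentile 99.2) and 0.24 (percentile 85.4), the latter -0.17 after median scaling. Over other processings their day 3 median fell as far as 0.13 and its percentile as far as 87.6, inside the central range. Lipogenesis had 0.29 (percentile 96.9; -0.49 after median scaling) and -0.08 (percentile 27.4; 0.06 with detection on every array), with Me1, which supplies NADPH, 5.73-fold and 3.97-fold higher. Glucose genes had 0.29 (percentile 95.8; -0.01 after median scaling) and 0.46 (percentile 99.9), or 0.38 (percentile 99.4) and 0.28 (percentile 95.6) with exchanged controls. Ppp1r3c, which directs glycogen storage, was 4.21-fold and 1.92-fold lower. Pck1, of glucose synthesis, was 4.75-fold and 2.85-fold higher (0.56 on its second probe at day 3) and G6pc, which releases glucose, 2.24-fold and 2.41-fold lower.

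Fetal and tumour markers had medians of 0.10 at day 3 (percentile 73.6; -0.25 with undetected signals at the lowest detected one and -0.49 with detection on every array) and 0.74 at day 5 (percentile 99.9), and Spink1, a trypsin inhibitor, was 4.43-fold and 8.99-fold higher. Lgals1, a galectin, was 4.58-fold and 2.01-fold higher, and Tubb2b, a tubulin, 2.94-fold lower at day 3; at day 5 its 2 detected probes disagreed (-1.66 and 1.42). Ly6d is on this list too and was its only call by limma over the list alone (adjusted p = 0.0276), lost without Ad-Med1 day 5. Hspa5, the chaperone of the ER, was at least 7.81-fold and 2.07-fold higher, while ER stress genes had -0.34 (percentile 4.25) and 0.34 (percentile 99.0; -0.23 after median scaling). Oxidative phosphorylation had 0.25 (percentile 99.7; -0.58 after median scaling) and 0.00 (percentile 57.9). Ribosome biogenesis had 0.10 (percentile 79.2; -0.05 after median scaling) and 0.15 (percentile 71.0; -0.02 with the mean of probes). Regeneration factors had -0.16 (percentile 26.4) and -0.11 (percentile 14.0; 0.01 with detection on every array and -0.59 after median scaling); Igf2, a fetal growth factor, was at least 1.88-fold and 4.43-fold higher and Hgf, the growth factor of hepatocytes, was at least 2.77-fold and 2.61-fold lower (-0.12 on a second probe at day 5).

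Plasma proteins of hepatocytes had medians of -0.05 (percentile 41.8) and -0.11 (percentile 20.4), but -1.35 and -1.67 (percentile 0 for each) after median scaling, and periportal genes -0.10 (percentile 35.5) and -0.15 (percentile 22.8; -1.23, percentile 1.89, after median scaling). B cell markers, 4 genes, had -0.02 (percentile 41.6; 0.05 with no filter) and -0.42 (percentile 9.21; 0.11 with no filter), and 3 cholangiocyte markers -0.29 (percentile 30.7; 0.05 with the mean of probes) and 0.16 (percentile 54.9; -0.01 after median scaling). At day 5 the erythroid list had 0.39 (percentile 89.4; -0.14 with the series values less their median difference) and the platelet list -0.18 (percentile 29.0; 0.11 with the mean of probes). Markers of other abdominal tissue, 4 genes, had -1.30 (percentile 0.13) and -1.26 (percentile 0.03). Over other processings the day 5 median reached -0.08 and its percentile 20.1, inside the central range. Cela2a, a pancreatic elastase, fell by 1.98 (bounds -1.76 and -0.74, since Ad-Med1 did not detect it), Cela1 by 1.62 and Car3, a carbonic anhydrase of fat and liver, by 1.16 on the log2 scale (adjusted p = 0.0255, 0.0255 and 0.0327 over the list alone). The calls of Cela2a and Car3 were lost without either Ad-Med1 array, and that of Cela1 without Ad-LacZ day 3 or Ad-Med1 day 5, in fits without the day term as elsewhere in this part. At day 3, with Ad-LacZ day 5 as the control, Acot3, Me1, Pck1, Hspa5 and Lgals1 stood at 1.24, 1.60, 0.99, 0.42 and 0.68. Susd4, a complement regulator, was the only called gene of the sex-biased list and fell by 2.52 (adjusted p = 0.0392), though Ad-Med1 detected it on neither day and the bounds were -1.37 and -1.44, a call lost without either Ad-Med1 array.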
